A study of Mus musculus with 20 samples.

How the data were processed

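Mitochondrial DNA (mtDNA) was sequenced from muscle stem cells of 20 mice, 4 at each of 5 ages, which were 2, 6, 12, 18 and 27 months. Per the labels, the mice were untreated wild-type C57Bl/6 animals. Muscle stem cells were sorted by flow cytometry for CD34, excluding cells positive for CD31, CD45 or Sca1 and cells stained by the viability dye DAPI. Total DNA was purified with a QIAamp kit, mtDNA was then enriched by amplification with a Repli-G mitochondrial kit, and Nextera XT libraries were made, per the labels' protocols. Because mtDNA was amplified before library construction, depth describes the amplified library and not the mtDNA copy number of the cells, and errors of the amplification are counted together with mutations.

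The deposited file of each animal lists 16299 mtDNA positions. Per the file headers, it gives at every position the count of reads with each base, in total and on each strand, the inserted and deleted sequences with their read counts, the total count and the count of mutated reads. These counts are raw whole numbers without normalization. The total equalled the sum of the bases, insertions and deletions at all positions of all animals. The deposited fraction of mutated reads is the mutated count divided by the total. It differed from the recomputed fraction by at most 5e-05 and was missing at up to 207 positions of an animal, all with a total of at most 9 reads, so it was not used further. The genome build was GRCm38, and FastQC 0.11.8, Trim Galore 0.6.4, Picard 2.23.1 and SAMtools 1.9.0 were used, per the submitters' processing notes. The aligner, the counting program and the minimum base quality are not given in the sources used here, and neither the labels nor the file headers mention molecular identifiers.

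Each library was assigned to its age and replicate number by its label. The design, the tests and most alternatives were fixed before the data were examined. The consensus base of a position was the most frequent base over all animals and equalled the reference base at all 16299 positions. The mutation burden of an animal was the mean, over positions with a depth of at least 100 reads, of the fraction of reads with a base other than the consensus, given per 10000 bases. The indel burden was computed likewise from inserted and deleted reads. A heteroplasmic site had a depth of at least 100 reads and a non-consensus base with at least 5 reads and at 1% or more. No upper limit was set, so near-fixed alleles were counted too. An allele called in 1 animal was termed private. The substitution spectrum left out sites at which an allele reached 10% in any animal. Base changes are written as the reference base, the position counted from 1 on the GRCm38 mtDNA, and the new base. Genes were located with a RefSeq table of the same build (GRCm38.p6), which lists 13 protein-coding, 2 ribosomal RNA and 22 transfer RNA genes. Gene symbols are those of that table. With the control region (positions 15423 to 16299) they made 38 regions, in lists fixed beforehand for complexes I, III, IV and V, ribosomal RNAs, transfer RNAs and the control region. Consequences in coding genes used the vertebrate mitochondrial code. Markers of other cell types were not used, since DNA was sequenced.

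Differences between 2 ages were tested with exact two-sided permutation tests of the means over all 70 relabellings of 8 animals, whose smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over the 4 older ages. Trends with age were tested with two-sided permutation tests of Spearman's rho (100000 permutations, smallest possible p 1e-05), adjusted over 6 measures. Single sites were tested with edgeR's quasi-likelihood test on non-consensus read counts with the log of depth as offset. Sites needed at least 100 reads in all animals, which 14550 did, and at least 20 non-consensus reads in total. All 5 ages entered the fit, with 15 residual degrees of freedom. Regional burdens were tested with limma on log2(fraction + 1e-06), and regional relative coverage with limma on the log2 ratio of the region's mean depth to that of the library, each with age in months as a linear term. The threshold was an adjusted p of 0.05. The nonsynonymous share of private alleles was compared with the share expected for the same substitution types at random coding positions by an exact binomial test, and shares of single animals have Wilson 95% intervals.

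The text names all protein-coding genes, the ribosomal RNAs, the transfer RNAs as a group and the control region. Single sites were named by a rule fixed beforehand. It took up to 10 higher and 10 lower sites with the largest log2 fold change among those past the threshold at 27 against 2 months, and up to 5 higher and 5 lower sites with the smallest p of the age trend. It also took the 10 alleles with the highest fraction in any animal and the 5 alleles called in most animals. The insertions and deletions named were chosen after their values were seen.

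Alternatives fixed beforehand were a minimum depth of 500 reads, allele thresholds of 0.5, 2 and 5%, thinning to the lowest depth of each site, at least 2 reads on each strand, and leaving out alleles called in over 10 animals, sites over 10% or the control region. Others were medians or pooled reads in place of means, DESeq2 or quasi-binomial regression in place of edgeR, no read minimum, age as a rank or only the compared ages, a pseudocount of 1e-05, 33 windows of 500 bp, Pearson's r, replicate numbers as a block, and leaving out each animal. Added after seeing the data were trends within 2 to 12 and within 18 to 27 months, values relative to each animal's overall burden, regional burdens without sites over 10%, trends without 12 months replicate 2 and 18 months replicate 1 together, the alternatives for 6, 12 and 18 against 2 months, the nonsynonymous share without each animal, the rule for the recurrent COX1 alleles, and heteroplasmic sites, regional burdens and the nonsynonymous share without them.

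The tests across sites were tested on simulated data with the real sites, depths and ages, in which all but 14219 of 14419 sites were changed by known sizes. At 27 against 2 months, 2.94% of sites raised 2-fold, 48.5% of those raised 4-fold and 90.9% of those raised 8-fold were recovered, and of lowered sites 0, 8.82 and 21.2%. In the age trend, 8.82, 66.7 and 90.9% of raised and 0, 14.7 and 30.3% of lowered sites were recovered. There was 1 false call among 14219 unchanged sites in each test. The 8-fold size was added after the first simulation. These counts were drawn with the same dispersion at every site, which real sites need not share. In the test of regions, all 8 of 8 changed regions were recovered without a false call. Its noise was independent between regions and smaller than that of the real regional burdens, so it says little about recovery in these data.

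Counts of the same site in animals of the same age differed by more than sampling noise in all 30 pairs (chi-square per site 1.59 to 27.1), so no library was counted as a duplicate. The deposited reads at N (0 in all animals) and the deposited fraction were left out. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Biopython 1.88, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.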

Results

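Mutations of the mtDNA were measured in muscle stem cells, the resident precursors of muscle fibres also known as satellite cells, of 20 mice. There were 4 animals at each of 2, 6, 12, 18 and 27 months of age. The mouse mtDNA of 16299 positions (GRCm38, mitochondrial chromosome) encodes subunits of respiratory complexes I, III and IV and of ATP synthase (complex V), and the ribosomal and transfer RNAs that translate them. Its non-coding control region (positions 15423 to 16299) holds promoters and the origin of heavy-strand replication. Mean depth per animal ran from 5087 reads per position (18 months replicate 1) to 9600.5 (6 months replicate 1). By age it was 8504 ± 1440.2, 8724 ± 689, 7726 ± 1130.1, 6149.7 ± 943 and 7269.7 ± 1789 reads (SD, n = 4 each). At the median depth of each animal, 3 reads corresponded to allele fractions of 0.0322 to 0.0610%. Intervals and such floors cover counting error only, since reads of amplified DNA without molecular identifiers are not independent molecules. Depth fell with age (Spearman's rho −0.509, permutation p = 0.0236, adjusted p = 0.0236, n = 20; Pearson's r −0.471, p = 0.0373). Without 2 of the 4 oldest animals, r lay between −0.740 and −0.312. Leaving out 2 months replicate 1, 2 or 3 gave a rho of −0.448 with permutation p of 0.0564, 0.0561 and 0.0561. The rank correlation of depth with age was −0.443 within 2 to 12 months (permutation p = 0.162; r −0.326) and 0.327 within 18 to 27 months (exact p = 0.486; r 0.412). No position of the animals of 2 and 6 months had fewer than 100 reads, whereas 378 ± 426, 608 ± 335 and 655 ± 798 positions did at 12, 18 and 27 months (up to 1620.0 in 27 months replicate 1).

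The first comparison asked how the mutation burden of muscle stem cell mtDNA differed with age. Non-consensus bases were rare up to 12 months and several times more frequent at 18 and 27 months. The burden was 3.71 ± 0.264 per 10000 bases at 2 months, 3.42 ± 0.0976 at 6 months and 5.13 ± 0.483 at 12 months, against 27.4 ± 9.26 at 18 months and 34.8 ± 2.54 at 27 months (SD, n = 4 each). At 27 months it exceeded the 2-month value 9.36-fold, by 31.0 per 10000 (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0381), with all 4 animals above all 4 young ones. At 18 months the burden was 7.37-fold and at 12 months 1.38-fold that of 2 months (exact p = 0.0286 and adjusted p = 0.0381 for both), and at 6 months the difference of −0.291 did not pass the test (exact p = 0.114). The step from 12 to 18 months was 5.33-fold (exact p = 0.0286), and that from 18 to 27 months 1.27-fold (exact p = 0.114). Of the 18-month animals, replicate 1 had a burden of 13.5 and the others 31.3 to 32.6.

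Across all animals the burden rose with age (Spearman's rho 0.883, permutation p = 3e-05, adjusted p = 4.5e-05, n = 20), a trend that rested on the step between 12 and 18 months. Because animals of 2 to 12 and of 18 to 27 months did not overlap, no Pearson's r over all animals is given. Alleles described below, near fixed at 27 months and rare up to 12 months, also set these ranges apart. Differences across the step therefore cannot be assigned to age rather than to mtDNA of another source, here or in later paragraphs. The rank correlation of burden with age was 0.562 within 2 to 12 months (permutation p = 0.0678; r 0.789, p = 0.00342; n = 12) and 0.546 within 18 to 27 months (exact p = 0.2; r 0.532, exact p = 0.114; n = 8). Measured as the median over sites, the difference of 12 from 2 months was 0.153 per 10000 (adjusted exact p = 0.486). That of 18 from 2 months was 16.8, or 7.06-fold (exact p = 0.0286, the smallest possible; adjusted exact p = 0.0571). Without any 1 of the 4 animals of 2 months, replicates 1 to 4, adjusted exact p rose to 0.0571 or 0.0762 for both ages.

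**Figure D1:**
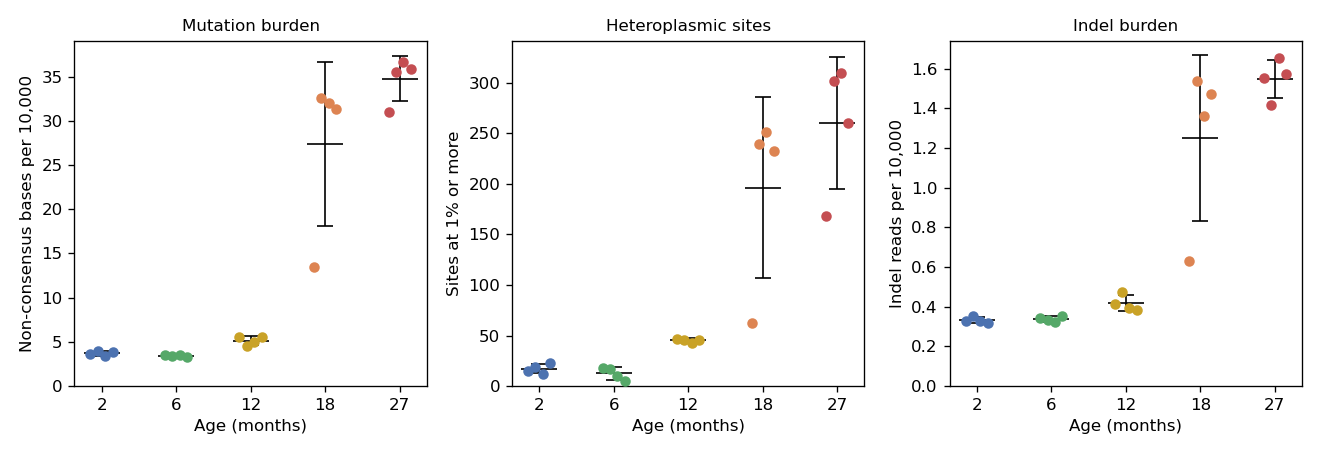
Mutation burden per 10000 bases, heteroplasmic sites per animal and indel burden per 10000 bases against age in months, with a point per animal and the mean ± SD of 4 animals per age. Mean burden stayed at 3.42 to 5.13 up to 12 months and reached 27.4 at 18 and 34.8 at 27 months, with 18 months replicate 1 at 13.5.

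Heteroplasmic sites, at which part of the mtDNA molecules carry another base, numbered 17.3 ± 4.79, 12.5 ± 6.14 and 45.5 ± 1.73 per animal at 2, 6 and 12 months, and 196 ± 89.8 and 260.0 ± 65.1 at 18 and 27 months. The 27-month count was 15.1-fold that of 2 months (difference 242.75, exact p = 0.0286, adjusted p = 0.0381; 4 of 4 animals higher), and the counts of 12 and 18 months were 2.64-fold and 11.4-fold (exact p = 0.0286, adjusted p = 0.0381 each). Neither 6 against 2 months (exact p = 0.314) nor 27 against 18 months (exact p = 0.343) passed the test. Of 777 alleles called in any animal, 684 were called only at 18 and 27 months, 40 only at 2 to 12 months and 53 in both age ranges. Complex I genes held 2.25 ± 0.957 called sites per animal at 2 months and 93.3 ± 34.3 at 27 months, and complex IV genes, which include COX1, held 14.8 ± 4.79 and 76.0 ± 9.90. Of these, 13.8 ± 4.79 at 2 months and 36 at 27 months belonged to a set of 36 recurrent COX1 alleles, each called in 10 or more animals. Without that set there were 3.5 ± 0.577 heteroplasmic sites per animal at 2 months and 224 ± 65.1 at 27 months, a difference of 220.5 (exact p = 0.0286) and 64-fold. At 12 months there were 18.5 ± 18.4 without it, 46 of them in the highest animal and 7 in the lowest, and at 18 months 160.3 ± 89.8. Replicate 2 of 12 months had 0 alleles of the set called and the other 3 animals of that age all 36. No called site lay in CYTB, the complex V genes, the ribosomal or the transfer RNAs at 2 months, against 17 ± 8.87, 13.5 ± 4.43, 29.5 ± 10.8 and 23.5 ± 7.51 at 27 months. In the control region 0.25 ± 0.5 sites were called at 2 months and 3 ± 0.816 at 27 months. The trend with age had a rho of 0.889 (permutation p = 3e-05, adjusted p = 4.5e-05), again resting on the step after 12 months. Within 2 to 12 months rho was 0.592 (permutation p = 0.0494, adjusted p = 0.136; r 0.826) and within 18 to 27 months 0.546 (exact p = 0.2; r 0.425).

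Private alleles, called in 1 animal each, numbered 438 of the 777. There were 0 at 2 and 6 months, 10 ± 19.3 at 12 months, 41.8 ± 30.1 at 18 months and 57.8 ± 39.1 at 27 months. At 12 months 39 of them were in replicate 2, and the other animals had 0 or 1. In animals of 18 and 27 months with 23 or more private alleles, their median share was 1.09 to 1.51%, just over the 1% threshold. A private allele may therefore be present below that threshold in other animals. The 27-month and 18-month counts differed from 2 months with an exact p of 0.0286 each, which the adjustment over ages raised to 0.0571. The trend had a rho of 0.839 (permutation p = 3e-05, adjusted p = 4.5e-05), while rho was 0.545 within 2 to 12 months (permutation p = 0.182; r 0.402) and 0.109 within 18 to 27 months (exact p = 0.886; r 0.256). Transitions made up 80.5 ± 4.03, 73.9 ± 11.1 and 68.4 ± 30.1% of called alleles at 2, 6 and 12 months and 87.3 ± 4.64 and 89.7 ± 3.63% at 18 and 27 months. This share rose by rank (rho 0.666, permutation p = 0.0019, adjusted p = 0.00228), but Pearson's r was 0.332 (permutation p = 0.154) and 27 against 2 months did not pass after adjustment (exact p = 0.0286, adjusted p = 0.114). Replicate 2 of 12 months had 23.4% transitions and the others of that age 80.9 to 86.0%. Within 2 to 12 months rho was 0.0148 (permutation p = 0.98) and within 18 to 27 months 0.327 (exact p = 0.486). The recurrent COX1 set made up 13.8 of 17.3 called alleles per animal at 2 months, 9 of 12.5 at 6 and 36 of 260 at 27 months. The transition share without this set is not given. Its rise therefore cannot be read as a rise among the other alleles.

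By type, T>C was the substitution that rose most by fold on the reference strand. The spectrum is not given without the recurrent COX1 alleles. T>C reads rose from 1.53 ± 0.0609 to 32.0 ± 3.76 per 10000 reads at T positions between 2 and 27 months, 21.0-fold. A>G rose 15.99-fold (1.34 ± 0.0414 to 21.4 ± 2.227), C>T 12.7-fold (1.85 ± 0.111 to 23.5 ± 1.98) and G>A 7.62-fold (2.38 ± 0.143 to 18.2 ± 1.46). The transversion A>T rose 9.11-fold, more than G>A, whereas C>A and G>T, types that oxidised guanine can give, rose 1.76-fold and 1.65-fold. Each of the 12 types was higher in all 4 animals of 27 months than in any animal of 2 months (exact p = 0.0286, adjusted over 12 types 0.0286). At 6 months 0 types passed the exact permutation test against 2 months, before or after adjustment (lowest exact p = 0.0857).

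**Figure D2:**
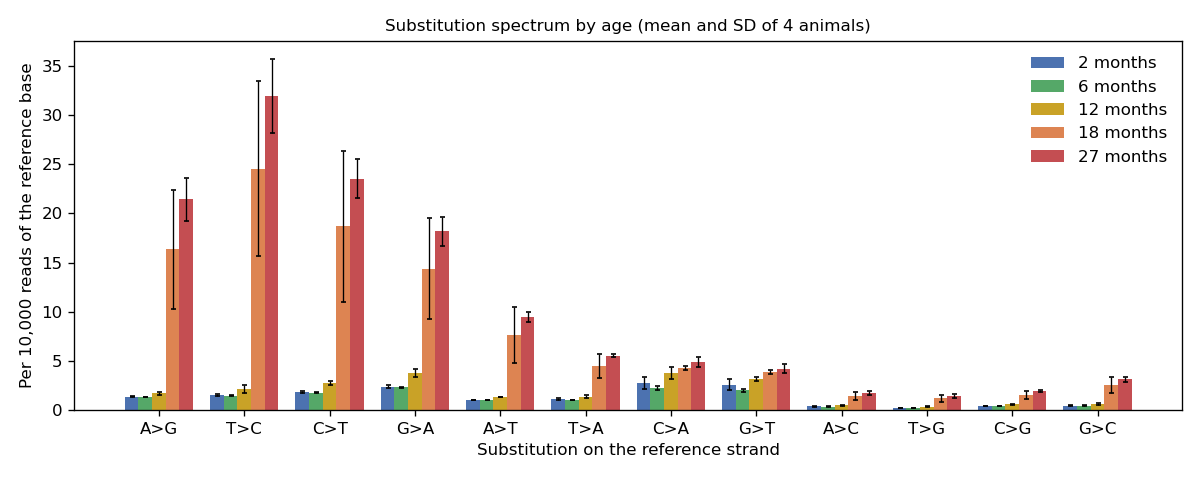
Reads with each of the 12 substitution types per 10000 reads of the reference base at each age, as mean and SD of 4 animals, without sites at which an allele reached 10% in any animal. T>C stood at 1.53 at 2 months and 32.0 at 27 months, and G>T at 2.56 and 4.23.

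The burden of small insertions and deletions together followed the same course at lower levels. The indel burden was 0.332 ± 0.0139 per 10000 at 2 months, 0.338 ± 0.0136 at 6, 0.417 ± 0.0400 at 12, 1.25 ± 0.420 at 18 and 1.55 ± 0.0975 at 27 months. It was 4.67-fold higher at 27 than at 2 months, 3.77-fold at 18 and 1.26-fold at 12 months (exact p = 0.0286, adjusted p = 0.0381 each), and 1.02-fold at 6 months (exact p = 0.543). The trend (rho 0.938, permutation p = 1e-05, the smallest possible; adjusted p = 4.5e-05) also held within 2 to 12 months (rho 0.798, permutation p = 0.00337, adjusted p = 0.0202; r 0.818) but not within 18 to 27 months (rho 0.655, exact p = 0.114; r 0.492). The insertion with the highest share lay in TrnR, the gene of transfer RNA arginine, after position 9828. It was in 0.424 ± 0.145, 0.398 ± 0.0521 and 0.547 ± 0.222% of reads at 2, 6 and 12 months, and in 50.2 ± 24.1 and 66.7 ± 3.595% at 18 and 27 months. How much of the rise in indel burden this insertion makes up is not given here. An insertion in ND2 after position 4059 went from 1.13 ± 0.282 to 4.82 ± 0.707% between 2 and 27 months, and one after position 5182, between TrnN and TrnC, from 7.70 ± 0.0985 to 12.1 ± 1.04%. Deletions varied more between animals. Between these ages that at 5177 went from 3.39 ± 3.91 to 1.13 ± 2.26%. Those at 5178 and 5182 went from 1.75 ± 3.49 to 11.4 ± 4.04% and from 5.28 ± 3.68 to 7.83 ± 4.41%.

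Several alleles that were rare up to 12 months were frequent in all animals of 18 and 27 months. T4891C, a synonymous change in codon 326 of ND2 (phenylalanine), a subunit of complex I, was at 0.0935 ± 0.0585, 0.1603 ± 0.0477 and 0.698 ± 0.763% at 2, 6 and 12 months. Its 12-month values ran from 0.0745 to 1.77%, and it was called in 1 animal of that age. It reached 78.8 ± 30.5% at 18 and 99.6 ± 0.279% at 27 months (SD, n = 4). T9461C, in the start codon of ND3 (codon 1, isoleucine), went from 0.565 ± 0.0850% at 2 and 1.17 ± 0.628% at 12 months to 78.4 ± 32.0 and 99.1 ± 0.206% at 18 and 27 months. In 18 months replicate 1, T4891C was at 33.4% (Wilson 95% interval 32.2 to 34.5, depth 6356) and T9461C at 30.8% (29.1 to 32.5, depth 2811). In the other animals of that age they were at 88.6 to 97.0% and 89.3 to 97.2%. Below them stood G5667T, which changes alanine to serine in codon 114 of COX1, the catalytic subunit of complex IV, at 0.0244 ± 0.0152% at 2, 19.7 ± 12.8% at 18 and 28.05 ± 5.31% at 27 months. T9820A in TrnR was at 0.116 ± 0.0224, 8.62 ± 3.32 and 9.88 ± 0.503%. It lies close to the adenine insertion after position 9828, which was at 0.424, 50.2 and 66.7% at these ages. Whether T9820A is independent of that insertion was not tested.

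**Figure D3:**
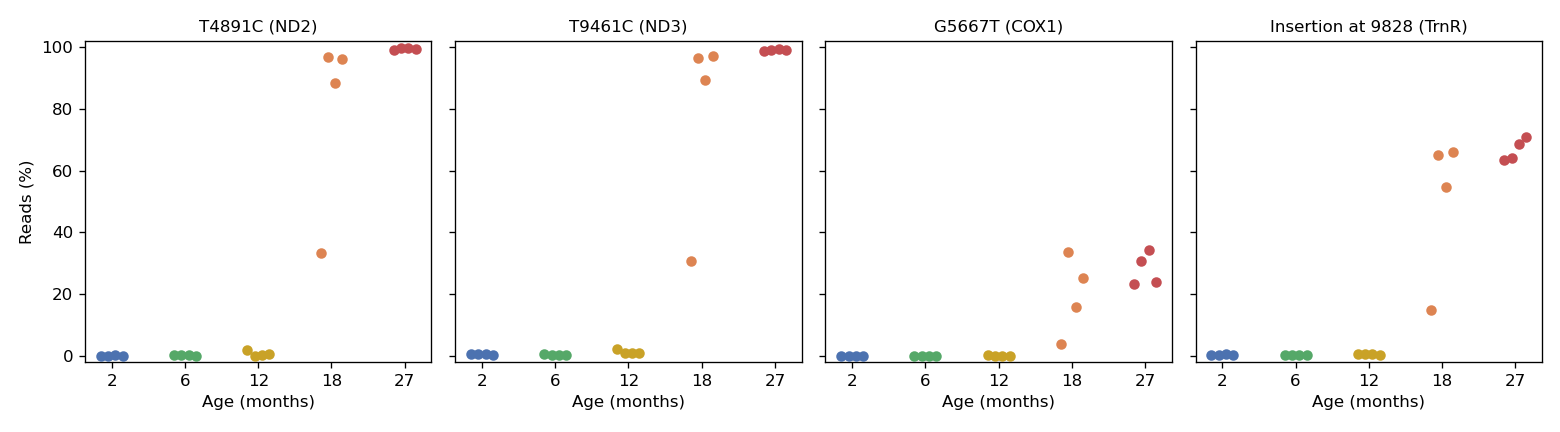
Percentage of reads with T4891C (ND2), T9461C (ND3), G5667T (COX1) and the insertion at position 9828 (TrnR) in each animal by age in months. Replicate 1 of 18 months, with T4891C at 33.4%, lies between the animals of 2 to 12 months and the other 18-month animals at 88.6 to 97.0%.

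Other named alleles were less frequent or present at all ages. C14024T (ND6, cysteine to tyrosine in codon 16) was at 0.0342 ± 0.0400% at 2 and 10.1 ± 5.66% at 27 months. The latter mean includes replicate 1 at 17.8% with a depth of 45 reads, under the minimum of 100 reads used for calls, and was 7.58% without it. T13141C (ND5, valine to alanine) was at 0.220 ± 0.148 and 6.58 ± 8.82%, with 19.1% over 141 reads in 27 months replicate 1, without which the mean was 2.40%. T13052C (ND5, synonymous) varied at 12 months, with 10.001% in replicate 1, 5.06% in replicate 2 and 0.182 and 0.181% in replicates 3 and 4 (mean 3.86%, or 1.81% without replicate 1), and was at 0.988 ± 0.148% at 27 months. A7259G (COX2, isoleucine to valine in codon 83) and A11157T (ND4, asparagine to tyrosine in codon 331) were called in all 20 animals. A7259G was at 3.51 ± 0.724, 3.58 ± 0.290, 5.89 ± 2.64, 5.38 ± 1.31 and 4.20 ± 0.844% at 2, 6, 12, 18 and 27 months. A11157T was at 3.40 ± 0.915 and 3.88 ± 0.884% at 2 and 6 months, 9.85 ± 4.25% at 12, 13.01 ± 3.59% at 18 and 14.2 ± 12.99% at 27 months. A11158T and T11160C, beside it in ND4, took a like course, from 1.2 ± 0.255 and 0.888 ± 0.211% at 2 months to 4.33 ± 1.16 and 2.78 ± 0.853% at 12, 5.54 ± 1.16 and 3.59 ± 1.05% at 18 and 6.51 ± 5.72 and 4.91 ± 4.26% at 27 months (A11158T 4.14% without 27 months replicate 1). At 12 and 18 months each of the 4 animals had more of these 3 alleles than any animal of 2 months. At 27 months replicates 1 and 2, at depths of 550 to 776 reads, had A11157T at 27.8 and 22.8%, A11158T at 13.6 and 8.67% and T11160C at 7.86 and 9.27%. In replicates 3 and 4 A11157T was at 3.66 and 2.54%, within the 2-month range of 2.36 to 4.51%, A11158T at 2.22 and 1.53% and T11160C at 1.28 and 1.22%. G5861A and G6620A, synonymous changes in COX1, were called in 19 animals each, at 1.38 ± 0.0960 and 1.12 ± 0.154% at 2 months and 4.02 ± 0.961 and 3.32 ± 0.991% at 27 months.

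The rise was spread over almost the whole mtDNA. Of 14419 sites tested, 12527 (86.9%) had a higher non-consensus fraction at 27 than at 2 months and 2 a lower one (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The median log2 fold change was 3.00 (quartiles 2.01 and 3.98). In protein-coding genes the share of sites that rose went from 82.4% (ND6) to 94.2% (COX1), and in mt-Rnr1 and mt-Rnr2, the genes of the small and large ribosomal RNA, it was 92.0 and 88.6%. In the control region 458 of 875 sites rose (52.3%), with a median log2 fold change of 1.40. Relative to each animal's overall burden, 1476 sites were higher and 1995 lower by the same test, and in the control region 24 and 440. The age trend called 12943 sites higher and 2 lower, of which 12434 were also higher at 27 against 2 months. By steps, edgeR called 0 sites at 6 against 2 months (484 at an unadjusted p under 0.05), 114 at 12 against 2 months (112 higher), 11569 at 18 against 2 months, 10487 at 18 against 12 months and 0 at 27 against 18 months (512 unadjusted). Within 2 to 12 months the trend called 107 of 11538 sites (105 higher), and within 18 to 27 months edgeR called 0 of 13788 (543 at an unadjusted p under 0.05).

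Among sites named by the size of their change, T4891C had a log2 fold change of 9.89 ± 1.03 (SE; edgeR adjusted p = 3.96e-17) and G5667T one of 9.49 ± 0.89 (adjusted p = 1.33e-19). C15017T in CYTB, the complex III subunit, was synonymous (codon 291) and reached 5.03 ± 1.11% at 27 months. Its site rose 402-fold over the 6 non-consensus reads at 2 months (log2 fold change 8.23 ± 0.70, edgeR adjusted p = 6.44e-23). T6018C (COX1 codon 231, tyrosine to histidine) reached 4.76 ± 1.15%, and its site rose 231-fold. At the sites of A9442T in TrnG, A1299G and A1306G in mt-Rnr2, A9867G in TrnR and A13061G in ND5 there were 0 non-consensus reads at 2 months. Against a floor of 3 reads over the pooled depth of that age (0.00811, 0.0124, 0.0123, 0.00821 and 0.0152%), they were at least 146-fold, 86.6-fold, 80.3-fold, 48.7-fold and 45.3-fold higher at 27 months. These sites exceeded all 2-month animals in 4 of 4 animals of 27 months, except A13061G, which did so in 3. A1791G in mt-Rnr2, with 2 non-consensus reads at 2 months, was at 0.776 ± 0.167% at 27 months. The trend also named A9714G in ND3 (threonine to alanine in codon 86), at 1.25 ± 0.451% at 27 months. The lower sites were those of C5045A in TrnA, the transfer RNA for alanine, and C10541A in ND4. C5045A went from 0.543 ± 0.210 to 0.0214 ± 0.00762% (log2 fold change of the site −2.48 ± 0.54, edgeR adjusted p = 1.24e-05). The site of C10541A went from 0.1003 ± 0.0536 to 0.00906 ± 0.0181% (log2 fold change −2.76 ± 1.21, edgeR adjusted p = 0.0268). The call of C10541A was lost in DESeq2 (adjusted p = 0.0626) and without 2 months replicate 4, 27 months replicate 1 or 27 months replicate 3 (adjusted p = 0.0759, 0.0736 and 0.0894), and without 27 months replicate 4 its log2 fold change was −4.90.

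Burden rose with age in 37 of the 38 regions (limma with Benjamini-Hochberg adjustment), the exception being TrnL1 (adjusted p = 0.104). TrnL1 went from 3.40 ± 0.524 to 20.7 ± 13.1 per 10000, 6.08-fold, with 4 of 4 animals of 27 months above all of 2 months, and all 38 regions passed with a pseudocount of 1e-05 or in the exact permutation test of 27 against 2 months. By list, the 7 complex I genes, the 3 complex IV genes, both complex V genes, CYTB, both ribosomal RNA genes, the control region and 21 of 22 transfer RNA genes rose, and the counts adjusted over the list alone were the same. ND3 had the largest ratio of 27 to 2 months among protein-coding genes, 22.5 (3.28 ± 0.313 to 73.9 ± 3.29 per 10000), which became 11.3 without its site of T9461C, and ND2 had 12.3, which became 9.42 without the site of T4891C. ATP6, COX3, ND6 and ND1 rose 11.4-fold, 11.1-fold, 10.96-fold and 9.95-fold, ATP8, ND4L, CYTB, ND5 and ND4 9.86-fold, 9.83-fold, 9.70-fold, 9.53-fold and 9.01-fold, and COX2 8.71-fold. COX1 rose 7.32-fold from the highest burden at 2 months (5.72 ± 0.417 to 41.9 ± 4.79), and 10.1-fold without the sites of its 36 recurrent alleles (3.53 ± 0.250 to 35.5 ± 3.25). The ribosomal RNA genes mt-Rnr1 and mt-Rnr2 rose 9.49-fold and 9.81-fold. TrnR rose 15.3-fold, which became 12.5-fold without its site of T9820A. The control region rose 3.43-fold, from 3.81 ± 0.324 to 13.1 ± 0.724. On this scale 26 regions changed within 2 to 12 months, and within 18 to 27 months limma called 0 regions (0 at an unadjusted p under 0.05).

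Relative to each animal's overall burden, 12 regions rose and 6 fell (limma adjusted p under the threshold), and the directions given next are on this scale. ND3, ND2, ATP6, COX3, ND6, ND1, ATP8 and CYTB rose, while COX1 (slope −0.0145 log2 per month, adjusted p = 0.0224) and the control region (−0.0667, adjusted p = 4.75e-06) fell. COX2, ND4, ND4L, ND5, mt-Rnr1 and mt-Rnr2 did not pass this test (limma adjusted p = 0.17, 0.746, 0.0667, 0.234, 0.125 and 0.072). With sites over 10% in any animal also left out, 19 regions rose and 6 fell by limma. ND4L, ND5, mt-Rnr1 and mt-Rnr2 then passed upwards (adjusted p = 0.0102, 0.0217, 0.0127 and 0.0072), and the control region still fell (−0.0640, adjusted p = 9.96e-06). Without the sites of the 36 recurrent COX1 alleles 9 regions rose and 9 fell by limma. COX1 then had a slope of 0.00334 (adjusted p = 0.0645) and ND1, ATP8 and CYTB no longer passed (adjusted p = 0.107, 0.276 and 0.246), while COX2 (−0.00619, limma adjusted p = 0.00815), ND4 (−0.00449, adjusted p = 0.0205) and the control region (−0.0705, adjusted p = 2.42e-06) fell. ND2, ND3, ND6, ATP6 and COX3 rose in this setting too.

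**Figure D4:**
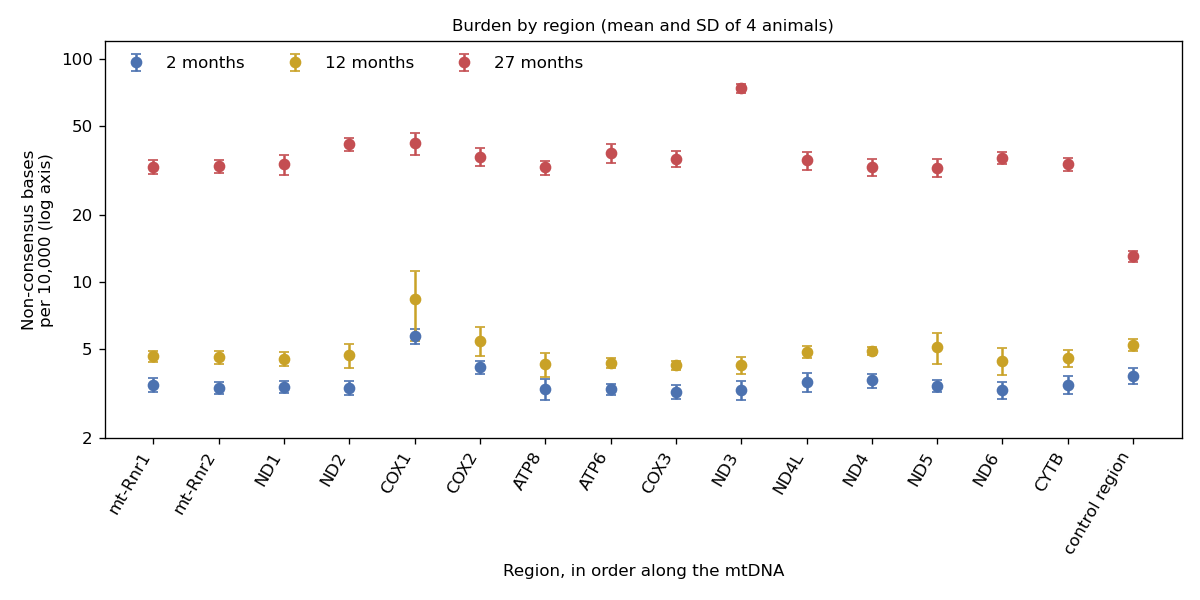
Mutation burden per 10000 bases of each region other than the transfer RNA genes at 2, 12 and 27 months on a log axis, as mean and SD of 4 animals per age. The control region rose from 3.81 to 13.1 and ND3 from 3.28 to 73.9 per 10000.

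The coverage of a gene relative to the whole mtDNA also changed with age, with a falling trend over stretches that hold the complex I genes. The trend passed for all 7 complex I genes (limma with Benjamini-Hochberg adjustment, all 7 also when adjusted over the list alone). Between 2 and 27 months the fitted log2 changes were −1.38 ± 0.24 for ND3 (SE, adjusted p = 0.000203), −0.36 ± 0.08 for ND2, −0.78 ± 0.22 for ND1, −0.74 ± 0.20 for ND4L, −0.67 ± 0.21 for ND4, −1.68 ± 0.63 for ND5 and −2.12 ± 0.76 for ND6. At 27 months ND2, ND3 and ND4L were below all 2-month animals in 4 of 4 animals and ND1 and ND4 in 3. ND5 and ND6 were so in only 2, and 1 animal was above them for ND5 (exact p = 0.371 and 0.257). COX2 (0.77 ± 0.16, limma adjusted p = 0.00068) and ATP6 (0.57 ± 0.18, limma adjusted p = 0.0137) gained coverage. Of complex IV genes 1 rose over all regions and over the list alone, and of the complex V genes 1 rose over all regions and 2 adjusted over the list alone. Among the 22 transfer RNA genes 3 rose and 9 fell, with the same counts when adjusted over the list alone. Those that fell lie in the same stretches as complex I genes. Their changes included −1.28 ± 0.23 for TrnG, −1.48 ± 0.27 for TrnR, −2.44 ± 0.79 for TrnH, −2.61 ± 0.81 for TrnL2 and −2.43 ± 0.81 for TrnE. The fall was thus not particular to complex I genes. CYTB (adjusted p = 0.0747), both ribosomal RNA genes and the control region passed neither limma test. In all, 21 of 38 regions changed, 5 upwards and 16 downwards. Without 27 months replicate 2 limma called 10 regions, losing ATP6, ND4, ND5 and ND6 (adjusted p = 0.055, 0.0555, 0.108 and 0.0814), and without 27 months replicate 1 ND5 and ND6 were also lost (adjusted p = 0.111 and 0.1). An exact permutation test of 27 against 2 months per region called 0 after adjustment and 10 before. Its smallest possible p of 0.0286 became 0.109 after adjustment for those 10. More regions at that smallest p would have been needed to pass, so the 0 says little. By limma, 12 regions changed within 2 to 12 months and 0 within 18 to 27 months (0 at an unadjusted p under 0.05).

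Of 359 private alleles in protein-coding genes, 237 changed an amino acid. This share of 66.0% (exact 95% interval 60.9 to 70.9) was close to the 66.4% expected of the same substitution types at random coding positions (exact binomial p = 0.911). By age, 94.1% of 34 alleles at 12 months, most of them from replicate 2, were nonsynonymous against 85.5% expected of their types (exact binomial p = 0.221). At 18 months it was 64.7% of 139 against 64.1% (exact p = 0.930) and at 27 months 61.8% of 186 against 64.6% (exact p = 0.444), with 0 private alleles at 2 and 6 months. Over all 614 called coding alleles the share was 60.3%, below the 65.9% expected (exact binomial p = 0.00376). This deficit rested on the 36 recurrent COX1 alleles, of which 4 (11.1%) were nonsynonymous, and without them the share was 63.3% of 578 against 65.6% expected (exact binomial p = 0.255). Among private alleles at 2% or more it was 63.2% of 38 (exact binomial p = 1).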

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

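In this part, every test of an explanation except that of forward against reverse reads was chosen after the results were seen. Within each age, animals were compared for 1 value far from the other 3. Of 113 sets of 4 animals, 12 had such a value, where 1 in 20 would be 5.65. The sets share animals and related measures, so they are not independent. The excess over 5.65 therefore does not measure a departure from chance.

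Replicate 1 of 18 months stood apart in 4 values. Its burden was 13.5 per 10000 against 31.3 to 32.6 in the other animals of that age, and it had 62 heteroplasmic sites against 233 to 251. T4891C in ND2 was at 33.4% against 88.6 to 97.0%, and T9461C in ND3 at 30.8% against 89.3 to 97.2%.

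The pattern behind these values was the step in burden between 12 and 18 months. Errors made in reading single molecules were argued against, since the T>C fraction of a site on forward reads ranked with that on reverse reads in the 27-month libraries (median rho over sites 0.857, against 0.306 at 2 months). Alleles that arose separately at random sites in each animal were argued against as the whole cause. The T>C fractions per site ranked alike in any 2 animals of 18 and 27 months (lowest rho 0.461, median 0.704). The rho of 2-month pairs (highest 0.149) is no fair yardstick. T>C was at 1.53 per 10000 reads at that age, so few reads per site hold rho low. The same limit applies to the 2-month rho of forward against reverse reads. A candidate explanation is mtDNA of another source, for example another colony's or a strain's mtDNA, marked by T4891C, and it stays open. In 18 months replicate 1 the excess over 2 months per site, as a share of that in the other 18-month animals, divided by the same share of T4891C, was 0.968. This ratio restates the burden and the T4891C share that set this 1 library apart, so it cannot decide, and age itself and a difference in amplification or library handling between ages, which the labels do not record, stay open and were not tested.

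Replicate 2 of 12 months had 39 private alleles against 0 to 1 in the other animals of its age, and 23.4% transitions against 80.9 to 86.0%. The same animal carried G5861A in COX1 at 0.0582% against 3.10 to 3.39%, and the mean of the recurrent COX1 alleles was 0.0371% in it against 2.00 to 2.20%.

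These recurrent alleles were 36 changes in COX1, each called in 10 or more animals, between positions 5381 and 6833, and 30 of them lay at the third position of a codon. Their mean share was 0.728 to 1.02% in animals of 2 and 6 months and 1.93 to 3.49% at 18 and 27 months. That 36 of the 36 alleles were at 0.2% or more in every animal of 2 months does not decide on separate origins in each animal, since the set was chosen by recurrence. Reads of a nuclear copy of mtDNA may account for them, as 88.9% were synonymous (exact 95% interval 73.9 to 96.9) where 29.5% was expected of these substitution types. A rise with age, a change in amplification and a mixture of mtDNA types stay open and were not tested, and why 12 months replicate 2 lacked the set was not tested either.

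Of the remaining values far from their group, G5861A was at 2.72% in 18 months replicate 4 against 3.44 to 3.57% in the others. T9461C was at 2.10% in 12 months replicate 1 against 0.784 to 0.998%. T13141C in ND5 was at 5.29% in 12 months replicate 4 against 0.0644 to 0.449%. C14024T in ND6 was at 0.0219% in 6 months replicate 2 (depth 4569), with 0 reads in the other animals of that age, which allow shares of up to 0.0618 to 0.108% (Wilson 95% limits).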

How the results depend on the processing

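Of the alternatives, those restricted to part of the ages, scaled to each animal's overall burden, with medians over sites for 12 and 18 against 2 months, with regional burdens without sites over 10%, or without the recurrent COX1 set, were chosen after seeing the data, as was leaving out animals for the nonsynonymous share. Counting each setting of each comparison once, 337 kept direction and side of the threshold, and 31 lost the call, 1 gained it, 7 changed direction and 5 moved in number. For single sites, regions and alleles these numbers were 1343, 31, 12, 12 and 0; where they did not, the cause was not tested unless stated. Restriction to 2 to 12 or to 18 to 27 months leaves fewer animals. Within 2 to 12 months rho was 0.562 for burden, 0.545 for private sites, 0.0148 for the transition share and −0.443 for depth; within 18 to 27 months it was 0.546 for burden, 0.546 for heteroplasmic sites, 0.109 for private sites, 0.327 for the transition share, 0.327 for depth, which changed direction, and 0.655 for indels. The trend of heteroplasmic sites within 2 to 12 months (rho 0.592) was counted as kept by its unadjusted permutation p of 0.0494. Its adjusted p was 0.136, so it did not pass the threshold used elsewhere. In the same restrictions the site trend called 107 and 0 sites, regional burden 0 within 18 to 27 months, and relative coverage 12 and 0 regions. With 12 months replicate 2 and 18 months replicate 1 set aside together, also chosen after seeing the data, all 6 trends kept their call. At an allele threshold of 5%, rho was 0.442 for private sites and 0.543 for the transition share. At the 1% threshold Pearson's r of that share was 0.332. As medians over sites, the difference from 2 months was 0.153 at 12 and 16.8 at 18 months, and the median gave no value for indels. Relative to overall burden, 3471 sites at 27 against 2 months, 5412 in the trend and 18 regions were called, with more sites lower than higher. The slopes of COX1, COX2, ND4 and the control region then turned to −0.0145, −0.00241, −0.000716 and −0.0667 log2 per month, and without sites over 10% those of COX1 and the control region were −0.0145 and −0.0640. Without the sites of the COX1 set, 18 regions were called on that scale, 9 of them lower, with slopes of −0.000364 for mt-Rnr1, −0.00619 for COX2, −0.00449 for ND4, −0.000283 for ND5 and −0.0705 for the control region. COX3 coverage had a slope of −0.00363 with median depth. The exact test called 0 regions for coverage, where its smallest possible p of 0.0286 became 0.109 after adjustment. The nonsynonymous share was 60.3% over all called alleles, 63.3% of these without the COX1 set, and 63.2% of private alleles at 2%. Leaving out each animal gave a rho of −0.622 to −0.448 for depth, burden differences from 2 months of −0.407 to −0.206 at 6, 1.28 to 1.62 at 12 and 21.9 to 28.3 at 18 months, a nonsynonymous share of 63.2 to 68.9% and 10 to 27 regions with changed coverage. The other comparisons kept their call without any animal: burden at 27 against 2 months 30.4 to 32.3, heteroplasmic sites 226 to 273, rho 0.866 to 0.903 for burden, 0.873 to 0.909 for heteroplasmic sites, 0.823 to 0.863 for private sites, 0.618 to 0.716 for the transition share and 0.930 to 0.954 for indels, 11814 to 12853 and 12438 to 13388 sites, and 37 to 38 regions. Replicate numbers did not pair the animals: of 40 same-number pairs, 17 for burden and 14 for depth by window correlated above 0.1, and 7 and 4 of 20 animals were closest to their own number. With the number as a replicate block, the differences of 31.0 in burden and 242.75 in heteroplasmic sites at 27 against 2 months had an exact sign-flip p of 0.125, the smallest that 4 pairs allow. No other comparison run with the block changed sides, and it called 12252 and 12715 sites and 37 and 20 regions. Burden at 6, 12 and 18 against 2 months was not run with it. Depth limits which alleles can be seen: below 0.0322 to 0.0610% an allele rests on fewer than 3 reads.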

Other observations

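All tests in this part except that of the end of the reference were chosen after the results were seen. In protein-coding genes, transitions at the third codon position were 2.36 ± 0.123 times as frequent as the mean of the first and the second position at 2 months and 1.31 ± 0.0469 times at 27 months (SD, n = 4; exact permutation p = 0.0286, adjusted over 4 ages 0.0571). This difference rested on the sites of the 36 recurrent COX1 alleles. Without them the ratio was 1.14 ± 0.0606, 1.11 ± 0.0444, 1.15 ± 0.129, 1.12 ± 0.0418 and 1.09 ± 0.0225 at 2, 6, 12, 18 and 27 months, and 27 against 2 months did not pass (exact p = 0.143, adjusted p = 0.571). With these sites, 12 months replicate 2, in which the set was at 0.0371%, had a ratio of 1.03 and the other animals of that age 2.97 to 3.10. Per 1000 sites, 14.7 heteroplasmic sites were called at 27 months in complex I genes, 14.9 in CYTB, 25.2 in complex IV (13.3 without the recurrent COX1 alleles), 16.03 in complex V, 11.6 in ribosomal RNA, 15.7 in transfer RNA genes and 3.42 in the control region.

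The insertions were runs of adenine. In TrnR after position 9828, 5214 reads over all animals had A inserted, 4579 AA and 640 AAA, while in ND2 after position 4059 single A made up 5119 reads, against 240 with AA and 28 with AAA. The private alleles of 12 months replicate 2 were of other types than those of older animals. C>A and G>T made up 31 of its 39 (79.5%), at a median share of 1.22%, whereas in 18- and 27-month animals with 23 or more private alleles they made up 0 to 2.82%. In 18 months replicate 1, 1 of only 2 private alleles was of these types.

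The control region rose less with age than any protein-coding gene. Base composition as the cause was argued against: with each substitution type compared separately, its excess at 27 months was at most 0.338 of that of the other sites in any of the 4 animals. Reads lost at the end of the linear reference were argued against too, since the ratio was at most 0.272 without the last 150 bases. In steps along the region, 27 months over 2 months was 2.5 to 4.43 up to position 16172 and 7.44 from 16173 to 16297. No biological explanation was tested.

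In 3 counts no other tried split or assignment of the animals to ages gave as many calls as the real one. For the sites in the trend and for relative coverage this argues against chance. It cannot exclude chance, since at most 100 splits or assignments were compared. For sites at 27 against 2 months, 1 of 35 splits of the 8 animals, the real one, gave as many (12529 sites, highest other 0). Every other split mixes animals of both ages, whose burdens lay far apart. The result thus restates that separation and cannot decide on chance. Of 60 assignments of ages drawn for the trend, the real one alone gave as many sites (12945, highest other 7966). For relative coverage it was 1 of 100 (21 regions, highest other 9). This last count is the weakest, since it fell to 10 regions without 27 months replicate 2. The exact permutation test of 27 against 2 months called 0 regions for coverage after adjustment. Its smallest possible p of 0.0286 became 0.109 there, so that 0 says little. For regional burden the real assignment also gave the most of 100, but 37 of 38 regions against 36 in another leaves no room to tell them apart, so chance stays open for this count. The burdens of the animals fell into 2 ranges, before and after the step at 12 to 18 months. Whether this accounts for the 7966 sites and 36 regions called in other assignments was not tested.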
